A study of Mus musculus with 3 samples.

How the data were processed

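Total RNA was extracted with Trizol and column purification, and libraries were made by the standard Illumina method, per the labels' protocols. The cells were B16F10, a mouse melanoma line. The table held 3 libraries, 1 of control cells and 2 of cells with Med23 knocked down, and all 3 value columns were used.

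The deposited values were RPKM, a read density scaled to transcript length and library size, computed by the authors. The submitters' processing notes name CASAVA 1.4, TopHat, Cufflinks and the mouse build mm9, with no role or order. The annotation, the filter on genes and the normalization step were not given in the sources used here. The values themselves showed more. After sorting, the 3 columns were equal (relative difference under 1e-09) in 95.3% of positions, and the largest relative difference was 0.687%, so the RPKM values had been quantile normalized across the libraries before they were deposited. Each column therefore summed to 255492 RPKM, with a median of 4.20 RPKM. Such values cannot show a change in the total amount of RNA, and they hold no read depth, so no counting interval could be given. The table listed 12852 genes and no value of 0. In it 78 symbols were carried by 2 gene IDs, so genes were handled by ID. The knockdown columns' names did not separate cleanly, so these columns were assigned to the group and are called the first and the second knockdown library by their place in the table, without saying which siRNA label each carries.

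Values were analysed as log2(RPKM + 1), and a log2 ratio on this scale understates the change of genes with low values. Genes with a mean of at least 1 RPKM over the 3 libraries were tested, 9722 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, from the 2 knockdown libraries alone, and a prior of 4.37 degrees of freedom. It takes the lone control library to vary like the knockdown libraries, an assumption these data cannot check. Genes changed at least 2-fold the same way in both knockdown libraries were therefore counted as well, with no test. Both knockdown libraries were compared with the same control, so correlations, covariances and overlaps are given beside values from 100 simulations of unchanged libraries.

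On simulated data with 200 of 9722 genes changed, the limma step recovered 70% of genes changed 1.5-fold and 100% of those changed 2-fold, 3-fold or 4-fold, and called 13 of 9522 unchanged genes. With a control that varied 3 times as much as a knockdown library it called 3318 of the 9522, and 48 were 2-fold in both libraries. Simulated genes of like expression were given the same normal spread, which real genes need not have. These rates therefore describe the simulated data and may not hold for the real libraries.

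Before the data were examined, 23 gene lists with 838 entries were fixed for pigmentation, Mitf targets, DNA repair, cell division, stress, metabolism, transcription and markers of other cell types, together with the design and the first set of other settings to be tried. Of the entries 748 matched 1 gene ID and 674 passed the filter. The list of mitochondrially encoded genes had 0 members in the table, which left 22 lists with at least 5 tested members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and then with an estimated correlation and with fry. None of the 9 camera calls held with an estimated correlation, which rests on 1 residual degree of freedom, and 1, interferon response, held with fry. A list's median was placed among 10000 random lists of the same size matched on mean expression.

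The rule for named genes, also fixed beforehand, took Med23 and Mitf, the 12 rises and 12 falls with the largest smaller change of the 2 libraries, up to 4 members of each list by the same measure, and a fixed set of pigment and repair genes. Alternatives were a pseudocount of 0.1, no filter or a minimum of 5 RPKM, rescaled or again quantile normalized libraries, no intensity trend, other fold limits, and each knockdown library left out. Added after seeing the data were a control SD of 2 or 3 times that of a knockdown library and a loess correction for transcript length and GC content. Length, GC, chromosome and gene type came from GENCODE M21, matched by gene ID for 12606 genes (98.1%). That annotation belongs to another build than mm9, so no coordinates are given. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.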

Results

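Gene expression was measured by RNA sequencing in B16F10 cells, a pigmented mouse melanoma line, after knockdown of Med23 with siRNA. Med23 encodes a subunit of Mediator, the complex that connects transcription factors with RNA polymerase II. The series held 1 library from control cells, titled siCtrl, and 2 libraries from knockdown cells. The values were RPKM for 12852 genes, and 9722 genes with a mean of at least 1 RPKM were tested. Read depth was unknown, because the values were RPKM that had been made equal in distribution across the libraries. The control had no replicate, so values are given as the control's RPKM against the mean ± SD of the 2 knockdown libraries. Nothing in the labels says whether the knockdown libraries came from separate cultures. The limma p-values take their spread from these 2 libraries and a prior drawn from all tested genes, with none from the control. The spread between the 2 libraries may be technical. Their column names, siMed23A and siMed23B, do not say whether A and B were different siRNAs or repeats, so this spread may also hold a difference between siRNAs. The p-values of camera with a preset correlation rest on the spread across genes, taken as nearly independent. They do not measure variation between cultures. The comparison asked, by the title of the series, whether Med23 bears on pigment genes and on DNA repair genes by way of Mitf.

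Med23 (ENSMUSG00000019984) was 5.23 RPKM in the control and 1.65 and 1.61 RPKM in the first and the second knockdown library, a mean of 1.63 ± 0.0294 (SD, n = 2). This was a 3.20-fold lower RPKM, and the log2 ratio on the log2(RPKM + 1) scale was -1.24 (SE 0.11, limma with Benjamini-Hochberg adjusted p = 0.0012). Mitf (ENSMUSG00000035158), the transcription factor that directs melanocyte development and pigment genes, fell from 9.00 RPKM to 4.23 and 3.51 RPKM, with a log2 ratio of -1.04 (SE 0.13, limma adjusted p = 0.0030). These p-values take the lone control to vary like the knockdown libraries, and when the control SD was taken as 3 times theirs neither gene passed, with adjusted p = 0.108 for Med23 and 0.186 for Mitf.

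Many pigment genes, 20 of the 34 tested, fell after knockdown. Tyr, the rate-limiting enzyme of melanin synthesis, dropped from 82.2 RPKM in the control to 9.83 ± 1.57 RPKM (SD, n = 2), a log2 ratio of -2.95 (limma adjusted p = 0.000239). Pmel, which forms the fibrils on which melanin is laid down, fell from 1712 to 567 ± 8.92 RPKM. Tyrp1 and Dct, enzymes downstream of tyrosinase, fell from 2306 to 882 RPKM and from 2359 to 1257 ± 55.8 RPKM. Mlana, a melanosome protein, fell from 359 to 137 ± 12.1 RPKM. The 2 knockdown values of Tyrp1 were identical, as were those of 15 of the 100 most abundant genes, because the distributions had been made equal, so the SD of the most abundant genes is understated. Of the 34 tested genes for melanin synthesis and the melanosome, 20 fell, 3 rose and 11 did not pass limma's test, and the counts adjusted over the list alone were also 20 and 3. The members that rose, named after their values were seen, were Slc6a15, Hps4 and Dtnbp1. Cited1, a transcriptional co-regulator, Slc45a2, a melanosomal transporter, and Mlph, which links melanosomes to the motor that moves them, were among the members with the largest falls, with log2 ratios of -2.88, -2.27 and -2.03. The median log2 ratio of the list was -0.77, below all 10000 random lists matched on expression. The list was lower than other genes by camera with a preset correlation (adjusted p = 2.05e-06), with an adjusted p = 0.830 with an estimated correlation. With the control SD taken as 3 times that of a knockdown library, 11 members were called lower and 0 higher.

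**Figure D1:**
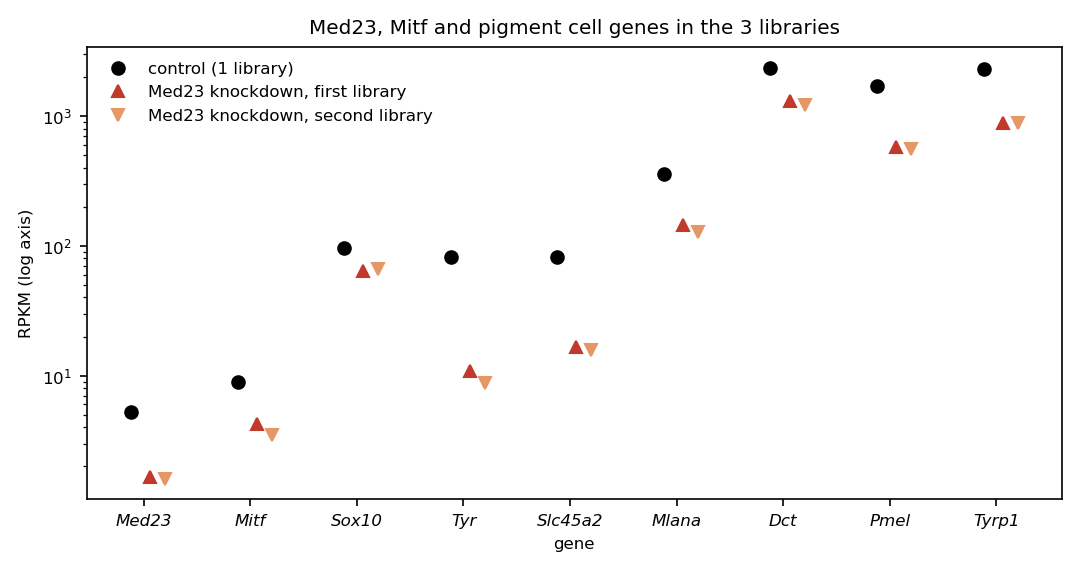
RPKM (log axis) of Med23, Mitf, Sox10 and 6 pigment genes in the control library (circles) and in the 2 knockdown libraries (triangles), with 1 point per library. Tyr was at 82.2 RPKM in the control and at 10.9 and 8.71 RPKM in the knockdown libraries, and the knockdown points of every gene shown lie below the control point.

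Genes for melanocyte lineage factors and receptors gave a less clear picture. Mc1r, the receptor for melanocyte-stimulating hormone, fell from 95.6 to 37.1 ± 1.33 RPKM, Pax3 from 42.5 to 22.3 ± 0.820 RPKM and Sox10 from 95.8 to 65.5 ± 1.82 RPKM. Snai2 rose from 1.15 to 2.76 ± 0.552 RPKM. Of the 9 members tested, 5 fell, 1 rose and 3 did not pass limma's test, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.0636, median log2 ratio -0.42). Under the 3 times larger control SD, 1 member was called lower. Among 22 other reported targets of Mitf, 13 fell, 3 rose and 6 did not pass, again with 13 and 3 adjusted over the list alone. Met, a receptor tyrosine kinase, fell from 162 to 34.6 ± 0.185 RPKM, Tbx2, a repressor of senescence genes, from 28.1 to 9.00 ± 0.704 RPKM, and Hif1a, the oxygen-regulated transcription factor, from 35.3 to 13.7 ± 0.846 RPKM. The members that rose were Apex1, Scd1 and Cdk4, of which Cdk4 was named after its values were seen. This list was lower by camera (adjusted p = 0.000446, median log2 ratio -0.49), with an adjusted p = 0.830 with an estimated correlation, and 2 members were called lower under the 3 times larger control SD.

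Genes of nucleotide excision repair, the pathway that removes ultraviolet lesions, moved in both directions. Xpa, which verifies the lesion, rose from 4.68 to 9.03 ± 0.149 RPKM, a log2 ratio of 0.82 (limma adjusted p = 0.00270). Ercc1, part of the nuclease that cuts on the 5' side, and Ercc2, a helicase of the general factor TFIIH, rose by log2 ratios of 0.65 and 0.56 (limma adjusted p = 0.0103 and 0.0171). Rpa1, which coats single-stranded DNA, fell from 47.0 to 24.4 ± 0.159 RPKM, and Cul4a, a ubiquitin ligase scaffold, fell from 17.6 to 9.23 ± 1.14 RPKM. Gtf2h1, Xpc, Ercc3 and Ddb2 did not pass limma's test. Gtf2h1, a TFIIH subunit, was 19.2 RPKM in the control and 18.1 ± 0.961 RPKM after knockdown. Of the 45 members tested, 10 rose, 8 fell and 27 did not pass, with 10 and 7 adjusted over the list alone, and none was changed 2-fold in both libraries. Of all tested genes 50.3% passed, a larger share than in this list or in the recombination, replication and mitosis lists described below. The median log2 ratio was 0.05 and camera did not call the list (adjusted p = 0.800). Of its members, 0 passed under the 3 times larger control SD.

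Other repair lists were likewise not called by camera. For base excision and mismatch repair, 8 of 23 genes rose, 5 fell and 10 did not pass limma's test, with 8 and 5 adjusted over the list alone (camera adjusted p = 0.393). Apex1, the main abasic site endonuclease, rose from 3.56 to 9.68 ± 0.0318 RPKM, and Fen1, a flap endonuclease, fell from 4.25 to 1.91 ± 0.0128 RPKM. For homologous recombination, the Fanconi pathway and end joining, 3 of 41 genes rose, 9 fell and 29 did not pass, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.279). Rad52 rose by a log2 ratio of 1.35, while Mdc1, Lig4 and Prkdc fell, with log2 ratios of -1.11, -1.16 and -1.26. Of 23 p53 targets and damage response genes, 9 fell, 4 rose and 10 did not pass, with 10 and 4 adjusted over the list alone (camera adjusted p = 0.165). Cdkn1a, an inhibitor of cyclin-dependent kinases, fell from 304 to 97.2 ± 0.216 RPKM, and Mdm2, Ccng1 and Trp53inp1 fell with log2 ratios of -1.31, -1.49 and -1.57. In the base excision and recombination lists 0 members passed under the 3 times larger control SD, and in the p53 list 1 was called lower.

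The genes with the largest rises in both libraries were mostly interferon-stimulated genes. Usp18, which restrains interferon signalling, rose from 0.496 to 22.2 ± 1.25 RPKM, Oas2, a sensor of double-stranded RNA, from 0.166 RPKM to 15.6 and 14.3 RPKM, and Isg15, a ubiquitin-like modifier, from 1.74 to 30.9 ± 0.200 RPKM. Their log2 ratios were 3.95, 3.78 and 3.54 (limma adjusted p = 7.98e-05, 0.000111 and 7.98e-05). Gbp2, Rtp4, Mndal, Irf7 and Mx2 rose with log2 ratios between 3.10 and 3.66. The other genes among the 12 largest rises were Hspa1b and Hspb1, which encode heat shock proteins, with H2-Gs10 and Gm10382. Hspa1b, Mndal and H2-Gs10 belong to families with near-identical copies, so their values are uncertain. Of 37 interferon response genes tested, 34 rose, 1 fell and 2 did not pass limma's test, with 34 and 1 adjusted over the list alone, and 32 rose at least 2-fold in both libraries. The member that fell was Ifit2, and those that did not pass were Trim25 and Eif2ak2, all named after their values were seen. Usp18, Oas2, Rtp4, Mndal, Irf7 and Mx2 were below 1 RPKM in the control. They passed the filter only through the knockdown libraries, so the filter favours genes that rose. The list's members under the filter, Oas3, Parp14 and Cmpk2, were also higher in both knockdown libraries than in the control. The median log2 ratio of the tested members was 2.04, above all 10000 random lists. Camera called the list (adjusted p = 2.06e-18), with an adjusted p = 0.830 with an estimated correlation, and fry, which asks whether the members moved one way on balance, gave an adjusted p = 0.0355. Under the 3 times larger control SD, 27 members were called higher. Markers of non-melanocytic cells stood at a median log2 ratio of 0.14, with 2 of the 6 tested members higher, 1 lower and 3 not past the test, the same counts adjusted over the list alone, and camera did not call them (adjusted p = 0.837), and 0 passed under the 3 times larger control SD.

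**Figure D2:**
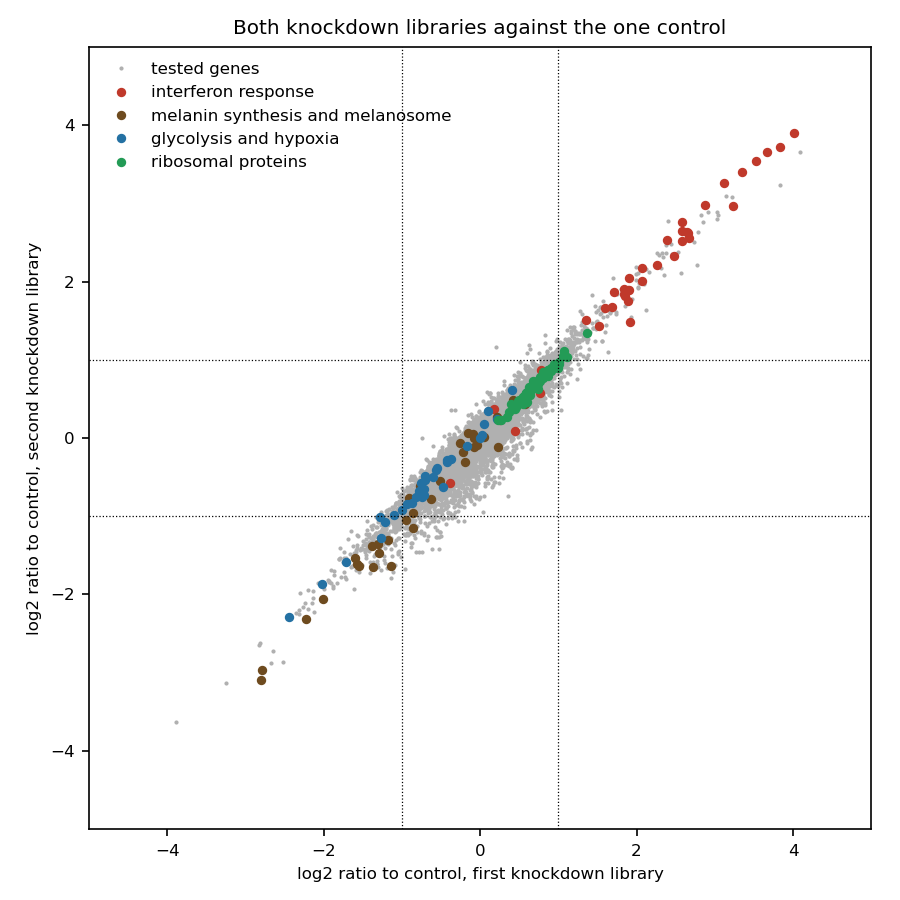
Log2 ratio to the control of each tested gene, on the log2(RPKM + 1) scale, in the first knockdown library (horizontal axis) and in the second (vertical axis), with 1 point per gene, 4 gene lists in colour and dotted lines at 2-fold. The points lie along the diagonal (correlation 0.959 across genes, against 0.501 simulated with no effect and a shared control, or 0.900 if the control SD is 3 times larger), with interferon response genes at the upper right and pigment genes at the lower left.

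The largest falls took in genes of energy metabolism and pigment. Ldhb, a subunit of lactate dehydrogenase, dropped from 71.3 to 4.34 ± 0.666 RPKM, a log2 ratio of -3.76 (limma adjusted p = 0.000162). Hk2, which phosphorylates glucose, fell from 51.8 to 9.29 ± 0.787 RPKM, and Slc16a3, a lactate exporter, from 74.3 to 13.9 ± 1.23 RPKM. Gsta4, a glutathione transferase, fell from 13.1 to 1.20 ± 0.359 RPKM, and Itgb3, an integrin chain, from 61.2 to 11.8 ± 0.399 RPKM. Tyr, Cited1, Syt4, Akap2, Rasd2, 5031439G07Rik and AF064781 made up the rest of the 12 largest falls, with log2 ratios between -3.19 and -2.68, and all 12 passed limma's test. Of 32 genes of glycolysis and the hypoxia response, 24 fell, 2 rose and 6 did not pass, with 25 and 2 adjusted over the list alone. Egln1, an oxygen sensor, fell from 131 to 33.4 ± 2.66 RPKM, Pfkp, a phosphofructokinase, from 103 to 32.2 ± 2.04 RPKM, and Bnip3, a mitophagy receptor, from 147 to 60.0 ± 0.236 RPKM. The members that rose, named after their values were seen, were Car9 and Pgk1. The median log2 ratio was -0.64 and camera called the list lower (adjusted p = 7.88e-08), with an adjusted p = 0.838 with an estimated correlation, and 9 members were called lower under the 3 times larger control SD.

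Genes of oxidative phosphorylation shifted by smaller amounts. Ndufs1, a complex I subunit, fell from 58.1 to 27.5 ± 0.816 RPKM, and Uqcrc1, of complex III, from 131 RPKM to 66.5 and 68.5 RPKM, whereas Cox7c, of complex IV, rose from 12.4 to 25.9 ± 0.167 RPKM. Of 51 members, 20 fell, 9 rose and 22 did not pass limma's test, with 20 and 9 adjusted over the list alone. The median log2 ratio was -0.14, and camera called the list lower (adjusted p = 0.0437), with an adjusted p = 0.830 with an estimated correlation and 0.108 without an intensity trend. Under the 3 times larger control SD, 1 member was called.

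All 61 ribosomal protein genes tested rose past limma's test, and all 61 also did when adjusted over the list alone, whereas 18 passed under the 3 times larger control SD. Rpl10a rose from 24.3 to 63.6 ± 0.712 RPKM and Rps20 from 63.0 to 132 ± 1.02 RPKM. The list's median log2 ratio was 0.68, and 4 members rose 2-fold in both libraries. Camera called it higher (adjusted p = 6.96e-24), with an adjusted p = 0.830 with an estimated correlation. Ribosomal protein genes have many near-identical pseudogenes, so their levels are uncertain where reads were split between copies. Across genes, log2 ratios fell with transcript length (Spearman -0.211) and rose with GC content (0.196), although genes are not independent replicates. The difference between the knockdown libraries (second minus first) followed GC content more closely (Spearman 0.344) and length less (0.0565), so GC content also set these 2 libraries apart. After a correction for length and GC the median of the ribosomal list was 0.55, with 58 of 61 members past the test.

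Immediate early genes, which respond within minutes to growth signals and stress, were more often higher than lower. Fos rose from 2.15 RPKM to 18.8 RPKM in each knockdown library, Jun from 22.8 to 98.4 ± 4.60 RPKM and Dusp1, a phosphatase of MAP kinases, from 3.97 to 18.9 ± 0.301 RPKM. Of 26 members, 17 rose, 4 fell and 5 did not pass limma's test, with 17 and 4 adjusted over the list alone. The members that fell, named after their values were seen, were Ier3, Mcl1, Dusp4 and Fosl2. The median log2 ratio was 0.85, and camera called the list higher (adjusted p = 0.000878), with an adjusted p = 0.838 with an estimated correlation. Under the 3 times larger control SD, 4 members were called higher and 1 lower.

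Enzymes of cholesterol and fatty acid synthesis were also more often higher, with 14 of 27 higher, 3 lower and 10 not past limma's test, and 15 and 3 adjusted over the list alone. Mvd, of the mevalonate pathway, rose from 4.11 to 11.5 ± 1.33 RPKM, Nsdhl from 6.06 RPKM to 14.4 and 15.5 RPKM and the desaturase Scd1 from 31.9 to 69.9 ± 9.28 RPKM. The members that fell, named after their values were seen, were Scd2, Acly and Elovl5. Camera called the list higher (adjusted p = 0.0195, median log2 ratio 0.43), with an adjusted p = 0.879 with an estimated correlation and 0.0644 when only genes of at least 5 RPKM were tested, and 1 member was called under the 3 times larger control SD. Of 22 replication-dependent histone genes in the list, 15 had values and only 5 passed the filter. All 5 tested rose, and all 5 did so adjusted over the list alone. Genes under the filter went both ways, such as Hist1h1e (0.272 RPKM in the control, 0.795 and 0.873 after knockdown) and Hist1h4c (0.256, then 0.226 and 0.249). Hist1h1c rose from 56.8 to 132 ± 1.63 RPKM, and the median log2 ratio was 1.20 (camera adjusted p = 0.00236, with an adjusted p = 0.830 with an estimated correlation), and 1 member was called under the 3 times larger control SD. Hist1h2ac and Hist1h2be were below 1 RPKM in the control and rose to 2.94 ± 0.469 and 2.34 ± 0.202 RPKM. They passed the filter only through the knockdown libraries, so the filter favours members that rose. Histone genes also share reads with near-identical copies.

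Lists for cell division and cell state were not called by camera. For DNA replication and S phase, 5 of 34 genes rose, 7 fell and 22 did not pass limma's test, with 4 and 7 adjusted over the list alone (camera adjusted p = 0.265). Rrm2, a ribonucleotide reductase subunit, fell from 34.9 to 15.6 ± 0.116 RPKM, and Ccne1, a G1 cyclin, rose from 13.5 to 22.6 ± 0.726 RPKM. For mitosis, 7 of 34 rose, 6 fell and 21 did not pass, with 7 and 5 adjusted over the list alone (camera adjusted p = 0.691). Cdc20 rose by a log2 ratio of 0.81, and Mki67 was 32.2 RPKM in the control and 20.6 and 11.4 RPKM in the knockdown libraries (limma adjusted p = 0.0409, which ranged up to 0.0742 under other planned settings). In the list for the mesenchymal or dedifferentiated melanoma state, 8 of 17 rose, 2 fell and 7 did not pass, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.229). Its largest rises were Fn1, an extracellular matrix protein, from 38.7 to 212 ± 10.0 RPKM, Jun, Ngfr and Axl, with log2 ratios of 2.43, 2.06, 1.32 and 1.19. The members that fell, named after their values were seen, were Tgfbr2 and Cd44. In the replication and mitosis lists 0 members passed under the 3 times larger control SD, and 3 of the mesenchymal list were called higher.

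Stress, lysosomal and transcription lists held large members in both directions. In the unfolded protein and amino acid stress list, 17 of 33 rose, 10 fell and 6 did not pass limma's test, with 17 and 10 adjusted over the list alone (camera adjusted p = 0.272). Nupr1 and Cebpb each rose by a log2 ratio near 1.57, and Sesn2 fell with a log2 ratio of -0.94. Of 45 lysosome and autophagy genes, 9 rose, 16 fell and 20 did not pass, with 9 and 16 adjusted over the list alone (camera adjusted p = 0.358). Naglu and Gusb, lysosomal hydrolases, fell, with log2 ratios of -1.17 and -1.11, whereas Map1lc3a and Ctsl rose, with log2 ratios of 0.98 and 0.93. The list's median was 0.02 and its mean -0.10, and the median turned to -0.04 after the length and GC correction. Of 31 Mediator subunits, 7 rose, 8 fell and 16 did not pass, with 7 and 8 adjusted over the list alone (camera adjusted p = 0.881, median log2 ratio 0.10, or -0.02 after the length and GC correction, mean -0.02). The 8 that fell include Med23 itself, the gene knocked down. Med22 rose from 6.44 to 17.4 ± 0.560 RPKM, and Cdk19, a Mediator kinase, fell from 9.79 to 4.59 ± 0.674 RPKM. Of 38 genes for RNA polymerase II and general transcription factors, 14 rose, 9 fell and 15 did not pass, with 14 and 9 adjusted over the list alone (camera adjusted p = 0.583). Polr2l rose by a log2 ratio of 1.28 and Gtf2e2, of TFIIE, fell with a log2 ratio of -1.21. Under the 3 times larger control SD, 2 stress genes and 1 lysosomal gene were called higher, 1 transcription gene lower and 0 Mediator subunits either way.

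**Figure D3:**
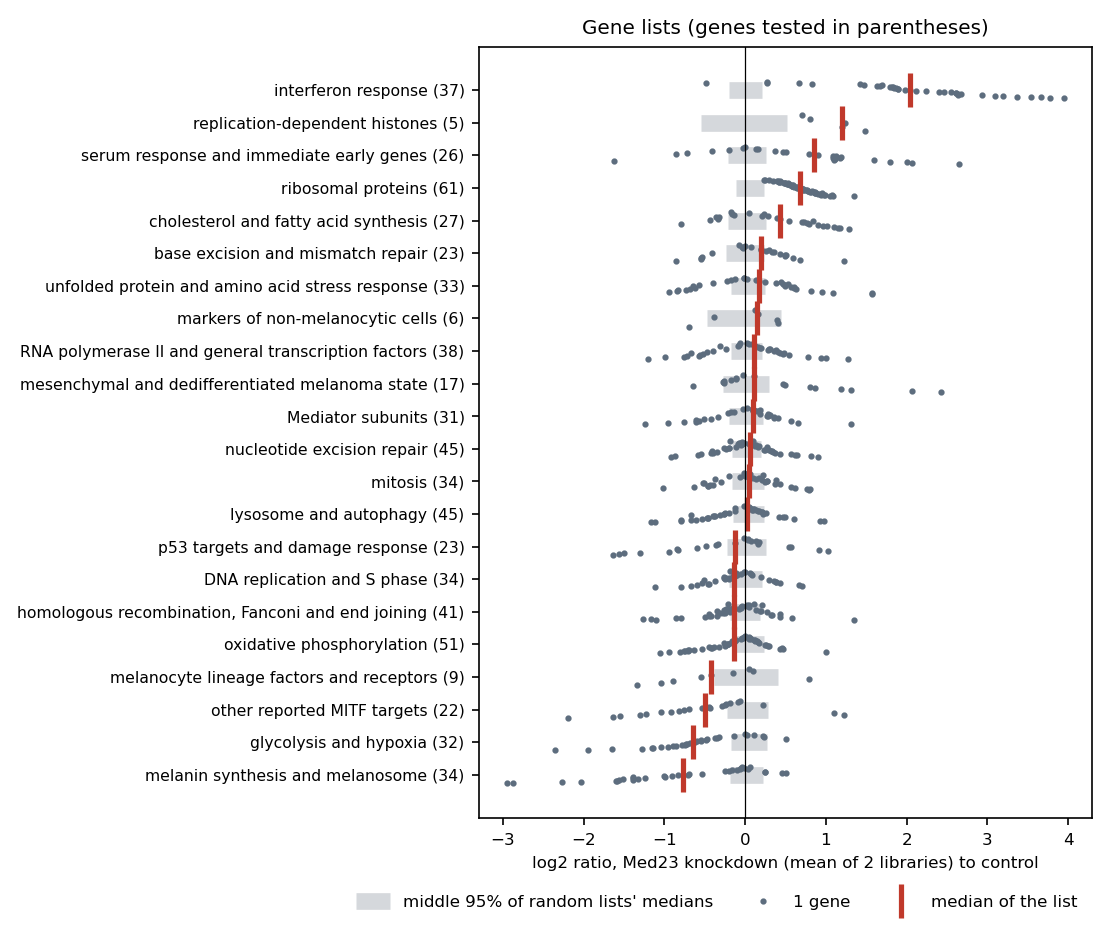
Log2 ratio of knockdown (mean of 2 libraries) to control on the log2(RPKM + 1) scale for each tested member (grey points) of 22 gene lists, with the list's median (red bar) and the middle 95% of the medians of random lists matched on expression (light band); vertical offsets within a list carry no value. Interferon response genes had the highest median (2.04) and melanin synthesis and melanosome genes the lowest (-0.77).

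Across all genes, 250 were at least 2-fold higher and 275 at least 2-fold lower in both knockdown libraries, 5.40% of those tested. Simulated unchanged libraries that shared a control gave 0 such genes in each of 100 simulations (a mean of 22.8 higher and 23.8 lower with a control SD 3 times as large), and independent lists of the same sizes would share 9.20 higher and 13.0 lower genes. The simulations gave genes of like expression the same spread, which real genes need not have. The libraries' log2 ratios had a covariance of 0.319, against 0.0138 simulated with no effect or 0.124 with a control SD 3 times as large, and 90.8% of genes had the same sign, against 66.6% simulated. Part of the excess may come from the shared control, which as 1 library could not be divided. The SD of the log2 difference between the knockdown libraries was 0.166, and 1 gene, Gm10491, named after its values were seen, was 2-fold apart between them. By limma, 2556 genes were higher and 2332 lower at an adjusted p under 0.05, of which 51.1% changed by less than 1.5-fold. With the control SD taken as 3 times that of a knockdown library, 118 were higher and 77 lower, and in simulated data with such a control the unadapted test called 34.8% of unchanged genes.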

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

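Among Med23, the 113 other genes chosen by the naming rule and the 22 lists fixed beforehand, none past its test changed direction under the alternatives run for it, which did not cover other genes or the lists added later. Among those not past it, 4 list medians changed sign, lysosome and Mediator after the length and GC correction (-0.04 and -0.02), lysosome also without either knockdown library, p53 targets at 5 RPKM or more (0.01) and mitosis without the first knockdown library (-0.08), as did 2 genes, Ercc3 and Xpc. The number of genes past limma depended most on the spread assumed for the lone control. With its SD taken as 2 times that of a knockdown library, an alternative chosen after seeing the data, limma called 810 genes higher and 683 lower, and with 3 times, 118 and 77. This setting changes only the SE and cannot move a log2 ratio. Dropping the intensity trend, estimating the correlation and using fry likewise leave log2 ratios and list medians as they were. None of these settings could therefore have changed the sign of a log2 ratio or of a median. At 3 times, Med23 (log2 ratio -1.24) had a limma adjusted p of 0.108, and 60 of the 113 other named genes lost their call, Mitf (adjusted p = 0.186) among them. With a pseudocount of 0.1 the genes 2-fold in both libraries numbered 446 higher and 440 lower, those 2-fold apart between the libraries 11, and the covariance was 0.492, since low genes then move more. Testing genes of at least 5 RPKM gave 1494 lower by limma and 3 lists higher, with fewer genes tested, and the melanocyte lineage list then passed camera (adjusted p = 0.0246). Requiring a 2-fold mean change beside the adjusted p left 293 higher and 346 lower. With 1 knockdown library left out, 298 to 300 genes were 2-fold higher and 347 to 363 lower, and 6 list medians moved by more than the spread between the libraries in each case. At 1.5-fold in both libraries there were 1016 higher and 970 lower, and at 3-fold 81 and 50. With an estimated correlation 0 lists were higher and 0 lower by camera, and with fry 1 and 0. The cause of these differences in list calls was not tested. Repeating the quantile normalization says little, because the deposited values already had it. No paired analysis was possible because the single control library has no replicate number to pair. Depth was unknown and sets no limit that could be computed here.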

Other observations

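The tests of other cell types, of the number of control libraries and of the control's spread were chosen after the results were seen, as were the 4 gene lists that follow and the length and GC correction. Targets of the oxidant-responsive factor Nrf2 and glutathione genes fell, with 19 of 25 lower, 1 higher and 5 not past limma's test and a median log2 ratio of -0.67. Txnrd1, a thioredoxin reductase, fell from 119 to 31.8 ± 2.12 RPKM (SD, n = 2), Hmox1, which breaks down heme, from 137 to 32.3 ± 2.95 RPKM, and Gclc, of glutathione synthesis, from 26.6 to 10.8 ± 0.676 RPKM. Of these, Hmox1 had been seen before, among the largest changes or in an earlier list, so its fall is not new support. Among the 19 members that were neither among the largest changes nor in an earlier list, 13 fell and 1 rose, with a median of -0.49 (camera adjusted p = 0.000839, and adjusted p = 0.393 with an estimated correlation). Genes of MHC class I and antigen processing rose, with 17 of 18 higher and 0 lower. B2m, the light chain, rose from 547 to 2256 ± 70.4 RPKM and H2-D1, a heavy chain with near-identical relatives, from 53.4 to 332 ± 11.7 RPKM. Both had been seen before, among the largest changes or in an earlier list, so their rises are not new support. Only 7 members had not been seen before, of which 6 rose (median log2 ratio 1.25, camera adjusted p = 0.00468, and adjusted p = 0.393 with an estimated correlation).

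A list of NF-kB targets and chemokines, which also holds genes of the pathway itself such as Rela and Traf2, gave 9 higher and 2 lower of 16. Cxcl1, a chemokine, was at 23.9 RPKM in the control and 177 ± 1.67 RPKM after knockdown. It had been seen before, among the largest changes or in an earlier list, so its rise is not new support. Of the 15 not seen before, 8 rose and 2 fell (camera adjusted p = 0.0210, and adjusted p = 0.394 with an estimated correlation). Heat shock proteins and co-chaperones split, with 11 of 23 higher and 8 lower and a median log2 ratio of 0.13 (camera adjusted p = 0.254). Beside the rises of Hspa1b and Hspb1, Hspa8 rose from 145 RPKM to 284 and 290 RPKM, whereas Hsp90aa1 fell from 171 to 97.8 ± 21.4 RPKM and Bag3 from 13.0 to 6.60 ± 0.829 RPKM.

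The rise of interferon response genes could come from the quantile normalization, from other cells, or from the transfected RNA or the culture. The normalization keeps ranks within a library, and the list's members moved up by a median of 32.2 percentile ranks, against at most 5.04 in random lists. With distributions made equal a value follows from its rank, so a list with this log2 ratio had to show such a shift. The comparison with random lists is therefore no separate test. A step that keeps ranks would not make the shift in rank, but the size of the rise before the normalization is unknown. Markers of other cell types had a median log2 ratio of 0.14 (SD 0.45), more than 1 SD below 1.02, the midpoint between 0 and the interferon median, which met the first criterion against such cells, but they were left open because only 6 of 34 markers could be tested. Of the myeloid markers, Lyz2 rose from 0.646 to 1.19 ± 0.00887 RPKM and Cd68 fell from 16.9 to 10.0 RPKM (limma adjusted p = 0.0305 and 0.00329, or 0.471 and 0.196 at the 3 times larger control SD), and Csf1r, below the filter, was 0.588 RPKM in the control and 0.271 and 0.457 RPKM after knockdown. A response to the transfected RNA or to the culture and not to the loss of Med23 cannot be told apart from an effect of Med23. The control was titled siCtrl, so transfection with an siRNA may be common to all libraries. A response particular to the Med23 siRNAs is not separated by such a control, and 1 control library gives no spread between transfections.

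The rise of ribosomal protein genes might follow from their short transcripts or their GC content. Their median log2 ratio of 0.68 lay above the highest of 10000 random lists matched on length and expression (0.36) and on GC and expression (0.29), which argues against either as the whole cause. A correction fitted without these genes left a median of 0.56. Reads shared with pseudogenes were not tested, and an effect of Med23 loss stays open.

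About 50.3% of tested genes passed limma's test. After the length and GC correction 5237 genes passed against 4858 before it, with 4296 passing both times, which met the criterion written against length and GC. This count cannot decide, because the correction also lowered the SD of the log2 difference between the knockdown libraries, from 0.166 to 0.143. The test takes its spread from that difference. The SD of the log2 ratios to the control fell from 0.570 to 0.551, a small part of their spread. Of 517 genes 2-fold in both libraries before the correction, 424 stayed so. A control library that varied more than the knockdown libraries cannot be told apart from broad change, because 1 library gives no spread, and 195 genes passed with its SD taken as 3 times theirs. The first criterion written for it, later replaced because a simulated setting excludes nothing, asked whether that multiple gave the 525 genes 2-fold in both libraries, and it gave a mean of 44.9 and at most 69, whereas 5 times gave a mean of 719. A different stock of cells in the control stays possible, since the SD of the chromosomes' median log2 ratios was 0.0554, against 0.0382 at the upper end of the middle 95% of shuffles (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). The medians were small, at most 0.15 on chromosome 7, the SD after the length and GC correction was 0.0553, and clusters of related genes would widen it too.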
